A study of Ambystoma mexicanum with 17 samples.

How the data were processed

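RNA was sequenced from explants of the oropharyngeal endoderm of axolotl (Ambystoma mexicanum) embryos, single-end, on an Illumina NextSeq 500. Per the labels' protocols, the explants were cut from the embryo at stage 15, kept in culture medium, and harvested when sibling whole embryos had reached stage 37/38, 39 or 41. The 17 libraries fall into 3 groups by the stage in their labels, with 6 libraries at stage 37/38, 6 at stage 39 and 5 at stage 41. The labels call the libraries replicates and do not say whether each came from separate embryos, pools or cultures, so p-values measure the spread between these libraries, which may be partly technical. The titles also carry letters that run from A to J and from K to R, each run holding all 3 stages. The labels do not say what the letters stand for, and they were used only as a possible batch.

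The submitters' processing notes name Trimmomatic, Bowtie2 and RSEM, without versions. Per the series' design text, counts of isoforms were collapsed to counts per gene with the gene to transcript map of a Trinity assembly. The deposited table holds expected counts, which need not be whole: 8.79% of the values above 0 were not whole numbers. The other file is the deposited map, whose gene and transcript identifiers are of no measured unit (other); it pairs 21244 transcripts with 19649 genes, of which 931 have more than 1 transcript. How the assembly was made, and its sequence, are not given in the sources used here. A gene below is therefore a Trinity gene, a cluster of assembled transcripts, and 7300 of the 19649 share an assembly component with another gene. Reads from near-identical sequences within a component could be divided between such genes, so their separate counts are uncertain.

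The files pair no identifier with a gene name, and 0 of the identifiers matched the reference table of gene symbols. Lists of genes for signalling pathways, cell types and cell functions had been fixed before the data were examined, with camera and fry tests for them. None of them could be tested without names.

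The expected counts were rounded to whole numbers. Total counts ran from 67834 to 748720 per library. Genes with too few counts were left out with edgeR's filterByExpr by stage at its default minimum count of 10, which kept 1985 genes holding 78.8% to 90.3% of the counts of a library. Library sizes were scaled by TMM. Each gene was fitted with 1 coefficient per stage over all 17 libraries with edgeR's quasi-likelihood model (glmQLFit and glmQLFTest), since stage is the only factor that the labels name. Tested were stage 39 against 37/38, stage 41 against 39, stage 41 against 37/38, any difference between the stages, and the later step minus the earlier step. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Standard errors of log2 fold changes are approximate, from the fold change divided by the square root of its F statistic. The pipeline was tested on simulated counts drawn from the means and library sizes of the data, with 200 genes changed per run in 5 runs. The calls it made held 1.73%, 2.66% and 3.03% unchanged genes for stage 39 against 37/38, 41 against 39 and 41 against 37/38. Each gene was drawn independently, so these shares leave out any structure that the libraries share.

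The rule for genes to be named, for files without gene names, took from stage 41 against 37/38 the 2 largest rises and the 2 largest falls among called genes with a mean of at least 10 CPM (counts scaled to a common library size) in the higher stage and every library of that stage above the median of the lower one. It was met by 0 genes. In its place the 2 genes with a higher and the 2 with a lower value at stage 41 that had the smallest unadjusted p are given, chosen after their values were seen, as were the 2 most abundant genes.

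Sample structure was described by Pearson correlations and principal components of log2 CPM with a prior count of 2. Stage was tested on the correlations with 100000 permutations of the stage labels. To compare the number of genes detected, each library was thinned without replacement to 60000 counts. Stage means of library measures were compared by two-sided exact permutation tests, 15 in 1 family with Benjamini-Hochberg adjustment. For genes with a count in every library, a set chosen after seeing the data, 95% intervals of the fold change were taken from limma-voom with sample weights. Shares in single libraries have 95% Wilson binomial intervals, and a group at 0 is set against a floor of 3 counts over the group. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

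The alternatives were DESeq2, limma-voom, scaling by DESeq2 size factors or by library size only, other filters on low counts, only the 2 stages compared, the replicate block, the letter runs as a term or 1 at a time, a test against a fold change of 1.5, and leaving out each library. Added after seeing the data were counts summed per assembly component, libraries of at least 100000 counts, leaving out stage 39 replicates 2 and 4 together, each other pair of stage 39 libraries for the genes called under some settings, DESeq2 with p adjusted over all tested genes, and the named genes under settings not planned for them. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.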

Results

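Oropharyngeal endoderm is the inner germ layer that lines the future mouth and throat, and in axolotls taste buds arise from it. Expression in explants of this tissue was measured by RNA-seq of extracted total RNA and is given as counts per Trinity gene. The 17 libraries hold 6 explant samples at stage 37/38, 6 at stage 39 and 5 at stage 41. Total counts in the deposited table were low and uneven, and the sources used here do not say whether the table holds all reads and all assembled genes. The total count per library averaged 201035 ± 128948 at stage 37/38 (SD, n = 6), 275874 ± 149963 at stage 39 (SD, n = 6) and 266232 ± 274559 at stage 41 (SD, n = 5). Between 3169 and 9900 genes had at least 1 count in a library. Of the 19649 genes in the table, 3548 had no count in any library, 2497 had counts in 1 library only and 458 had counts in all 17. These 458 genes took 60.7% to 77.8% of the counts of a library.

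The most abundant genes were shared by all stages. TRINITY_DN28458_c0_g3 took 14.6% ± 5.29 of the counts at stage 37/38 (SD, n = 6), 17.7% ± 10.2 at stage 39 (SD, n = 6) and 16.5% ± 3.24 at stage 41 (SD, n = 5). Its share ran from 8.06% in stage 39 replicate 3 (Wilson 95% interval 7.92% to 8.20%) to 33.8% in stage 39 replicate 4 (Wilson 95% interval 33.6% to 34.0%). TRINITY_DN28458_c0_g1, from the same assembly component, took 10.4% ± 4.48, 11.95% ± 3.84 and 11.5% ± 4.28 at the 3 stages in the same order. Since both belong to 1 component, the division of reads between them is uncertain. The 10 most abundant genes of each library together held 26.5% to 57.2% of its counts. Total counts, genes detected in 60000 counts, the share of the 10 most abundant genes and the shares of these 2 genes differed between stages by less than the spread between libraries, with adjusted p = 0.9524 in each of 15 exact permutation tests. The unadjusted p-values of these tests lay between 0.3636 and 0.9524.

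**Figure D1:**
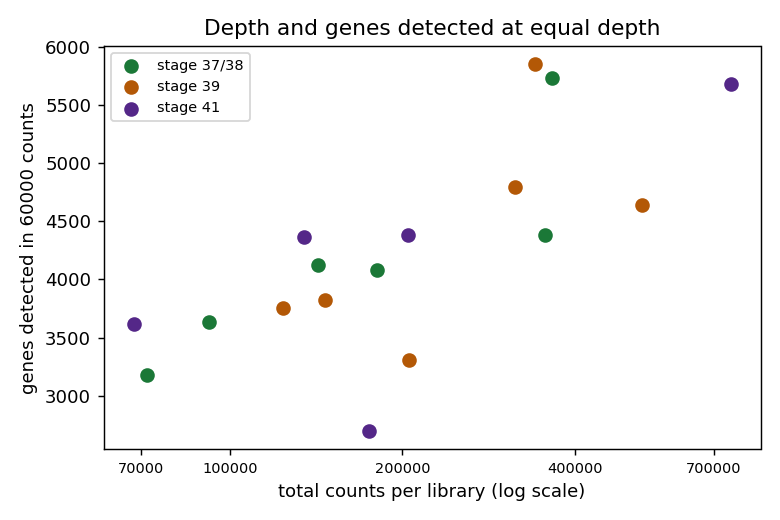
Each point is 1 of the 17 libraries, with its total count on a log scale against the number of genes detected after thinning to 60000 counts, coloured by stage. The number ran from 2696 to 5848, and the 3 highest values, 5848, 5729 and 5677, came from 1 library of each stage.

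The libraries did not group by stage. Over the 1985 tested genes, the 136 pairs of libraries had Pearson correlations of log2 CPM between 0.303 and 0.796 with a median of 0.502, which are correlations across genes and not across independent replicates. The mean correlation was 0.502 for pairs of 1 stage and 0.505 for pairs of different stages (one-sided permutation p = 0.562). Pairs from the same run of title letters averaged 0.509 and pairs from different runs 0.4997. The 3 most similar pairs joined stage 37/38 replicate 1, stage 39 replicate 5 and stage 41 replicate 2, the libraries with the most genes at equal depth, with correlations of 0.796, 0.759 and 0.749. The first principal component held 16.2% of the variance and the second 9.90%.

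**Figure D2:**
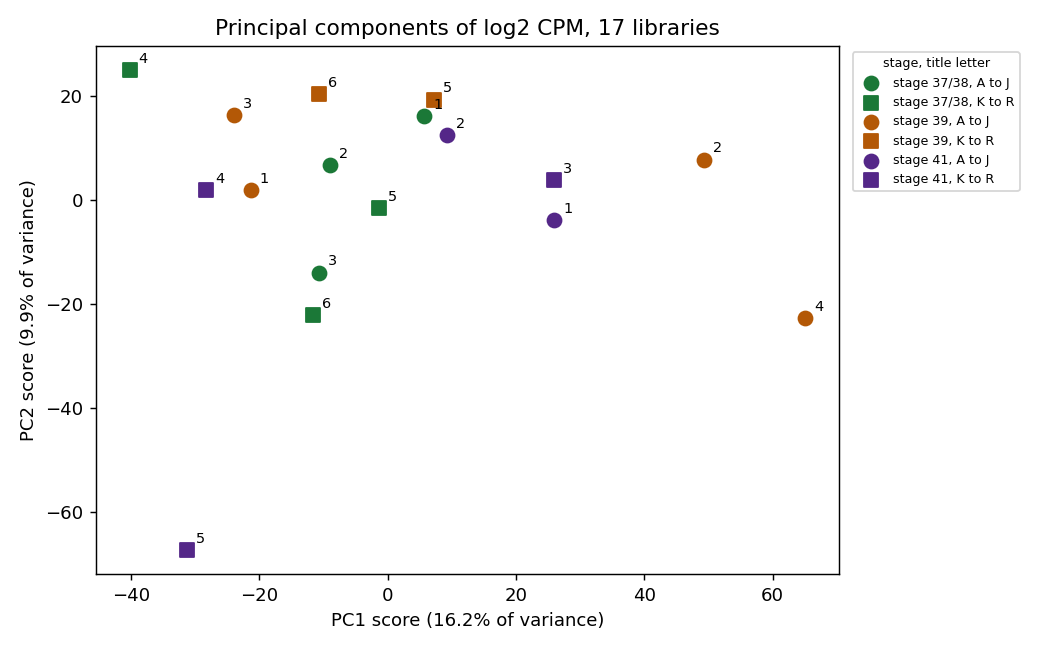
Scores of the 17 libraries on the first (16.2% of variance) and second (9.90%) principal component of log2 CPM, coloured by stage, with circles for title letters A to J, squares for K to R, and replicate numbers beside the points. Stages overlap, and stage 39 replicates 2 and 4 lie farthest to the right, at 49.3 and 65.1.

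A set of genes was high in a few libraries of stages 39 and 41. In stage 39 replicate 2, 95 of the 1985 genes lay at least 8-fold above their median over the 17 libraries, and in stage 39 replicate 4, 124 did. The libraries shared 63 of these genes, and no other of the 136 pairs shared more than 31. This is 10.6 times the 5.94 that independent lists would share, but independence is not the level found between libraries: the median ratio of the other 135 pairs was 6.74, and 32 of them had a ratio at least as large, up to 55.6 in pairs with few such genes. The 63 genes took 9.51% and 11.1% of the counts of these libraries, 3.13% in stage 41 replicate 1 and 3.16% in stage 41 replicate 3, and 0.316% to 1.86% in the other 13 libraries. Of the 63, 24 were also at least 8-fold above their median in stage 41 replicate 1 and 22 in stage 41 replicate 3, against 0 to 3 in each of the other 13. The set was picked from the data for its level in those stage 39 libraries, so its level there is no test. The 8-fold limit was applied to TMM-scaled values. Stage 39 replicates 2 and 4 had the lowest TMM factors, 0.632 and 0.470, against 0.828 to 1.39 in the other libraries. A low factor raises all scaled values of a library and so may raise its number of such genes. The shares of counts are unscaled.

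**Figure D3:**
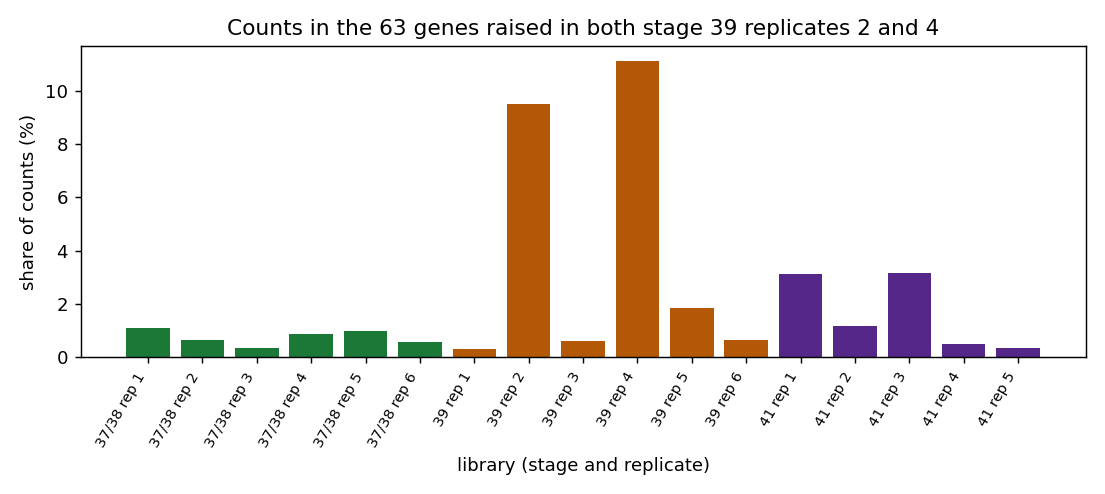
Bars give the share of each library's counts, in percent, that fell in the 63 genes at least 8-fold above their median in both stage 39 replicates 2 and 4, coloured by stage. Those libraries reach 9.51% and 11.1%, stage 41 replicates 1 and 3 reach 3.13% and 3.16%, and the others stay at or below 1.86%.

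Stage 39 was compared with stage 37/38 to find genes whose expression differed over the earlier step of culture. Of the 1985 genes, 0 passed the threshold in edgeR's quasi-likelihood test, with 87 at an unadjusted p under 0.05. A flat distribution of p would give 99.25, and other groupings of the same libraries gave a median of 74. DESeq2 called 17 genes, all higher at stage 39, and limma-voom 0. TRINITY_DN27721_c0_g1 had 12.5 ± 21.9 CPM at stage 37/38 (SD, n = 6) and 252 ± 228 at stage 39 (SD, n = 6), with counts in 3 of 6 and 6 of 6 libraries. Its log2 fold change of 4.61 (SE 1.48) had an adjusted p of 0.6129 in edgeR, with 4 of 6 stage 39 libraries above every stage 37/38 library. The gene with the smallest p in this comparison (log2 fold change 6.97, SE 1.68, edgeR adjusted p = 0.6129) had 6127 CPM in stage 39 replicate 2, 12390.1 in replicate 4, 917 in replicate 5 and 0 to 140 in the other 3 libraries of its stage, against 0 to 107 at stage 37/38. DESeq2 adjusted p over 675 genes there, and 5 of the 17 passed when p was adjusted over all genes with a p. With stage 39 replicates 2 and 4 left out, a pair chosen after seeing the data, DESeq2 adjusted over 2276 genes and called 2, of which 0 were among the 17. All 17 were still tested, their median log2 fold change went from 4.92 (median SE 1.36) to 0.81 (median SE 1.31), and 0 passed with p adjusted over the genes of the first fit. With each of the 6 pairs of other stage 39 libraries left out, that median was 5.40 to 5.45 and 15 to 17 of the 17 were called. With the 8 pairs that hold only 1 of replicates 2 and 4 it was 3.83 to 4.98, and 0 to 2 of the 17 were called. With p adjusted over the genes of the first fit, these counts were 16 to 17 for the 6 pairs and 0 to 6 for the 8. With the more permissive filter of 5 CPM in 5 libraries edgeR called 34 genes, and 28 of these had over 50% of their summed CPM in the same 2 libraries.

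Stage 41 was compared with stage 39 for the later step. In edgeR 0 of 1985 genes passed the threshold, with 47 at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. With the filter of 5 CPM in 5 libraries edgeR called 4 genes, all lower at stage 41, and without a filter 10, of which 9 were lower. Leaving out stage 39 replicates 2 and 4 gave 2 and 5 under these filters, and neither count was set against other splits of the libraries. TRINITY_DN85_c0_g1 had 917 ± 1003 CPM at stage 39 (SD, n = 6) and 36.6 ± 35.6 at stage 41 (SD, n = 5), and 4 of 6 stage 39 libraries lay above every stage 41 library. Its log2 fold change of -4.58 (SE 1.51) had an adjusted p of 0.9989 in edgeR. TRINITY_DN27941_c0_g1 had 41.05 ± 30.97 CPM at stage 39 and 4.63 ± 7.70 at stage 41, with counts in 6 of 6 and 2 of 5 libraries (log2 fold change -2.66, SE 1.25, edgeR adjusted p = 0.9989).

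Stage 41 was compared with stage 37/38 for the whole interval. Again 0 of 1985 genes passed the threshold in edgeR, with 53 at an unadjusted p under 0.05 and a smallest adjusted p of 0.9997, and DESeq2 and limma-voom called 0. TRINITY_DN27721_c0_g1 had 412 ± 617 CPM at stage 41 (SD, n = 5), and its log2 fold change against stage 37/38 was 5.32 (SE 1.53, edgeR adjusted p = 0.9997). That value was 3.85 without stage 41 replicate 1 and 6.72 without stage 37/38 replicate 4. It was above every stage 37/38 library in 3 of 5 stage 41 libraries and had no count in the other 2. TRINITY_DN31429_c0_g2 had no count in 6 of 6 stage 37/38 libraries, where 3 counts over the group would be 2.57 CPM. It averaged 166 ± 226 CPM at stage 39, with counts in 3 of 6 libraries, and 271 ± 472 at stage 41, with counts in 2 of 5. The stage 41 mean over libraries was 106 times that floor (edgeR adjusted p of the gene = 0.9997). The floor pools the counts of its group, so this ratio is no strict lower bound. The stage 41 mean rests on 1090 CPM in replicate 3 and 268 in replicate 2, and the median there was 0. TRINITY_DN85_c0_g1 had 1450.0 ± 1548 CPM at stage 37/38 (SD, n = 6), with 4 of 6 libraries above every stage 41 library and no count in replicate 1 (log2 fold change -5.24, SE 1.56, edgeR adjusted p = 0.9997). Its log2 fold change was -5.85 without stage 41 replicate 1 and -1.93 in limma-voom. TRINITY_DN27941_c0_g1 had 109 ± 96.7 CPM at stage 37/38 (SD, n = 6), with 5 of 6 libraries above every stage 41 library (log2 fold change -4.07, SE 1.33, edgeR adjusted p = 0.9997, and -5.68 without stage 41 replicate 2). These 4 genes are the pairs with the smallest unadjusted p in either direction, so their values are extremes of 1985 genes. With the filter of 5 CPM in 5 libraries edgeR called 8 genes in this comparison, among them the first 3 of these 4, with adjusted p of 0.00928, 7.2e-05 and 5.6e-05, and 15 of 100 splits of the same libraries called as many as 8. Of the 8 genes, 6 were also tested under the default filter and were not called there.

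**Figure D4:**
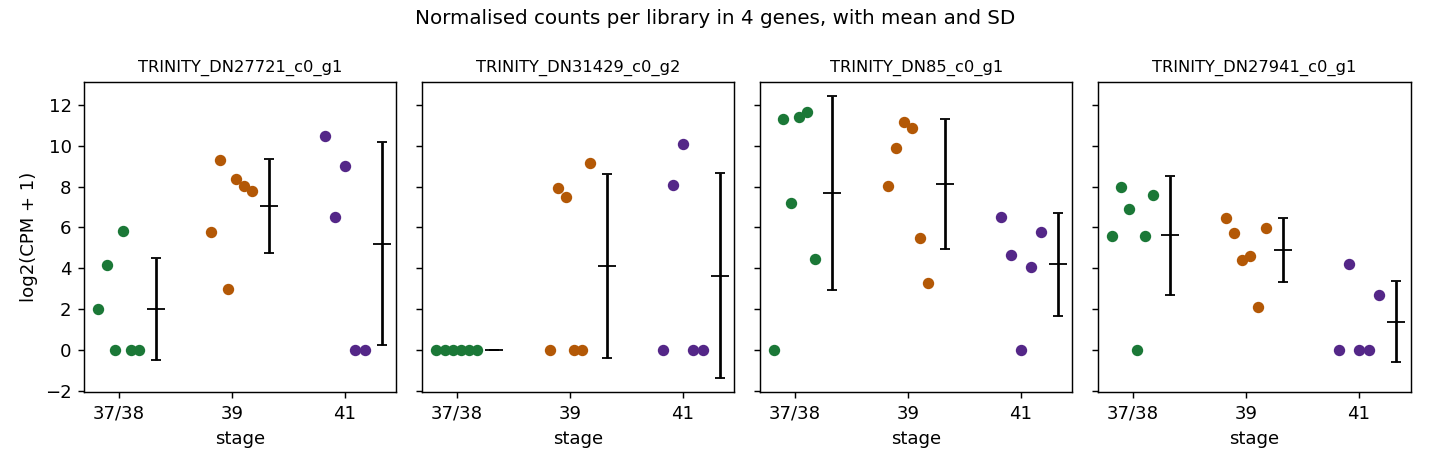
Points give log2(CPM + 1) of 4 genes in each library by stage, with 6, 6 and 5 libraries, and the black line beside each group gives the mean and SD on that scale. The SD bars of neighbouring stages overlap in most panels, and every gene has libraries at 0 in at least 1 stage.

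The tests of any difference between the stages and of the later step minus the earlier step also gave 0 called genes in edgeR, with 69 and 89 genes at an unadjusted p under 0.05. Limma-voom called 0 in both, and DESeq2 0 and 1. Without a filter on low counts edgeR called 68 genes for any difference and 81 for the later minus the earlier step, 79 of them lower. Leaving out stage 39 replicates 2 and 4 gave 13 and 2 without a filter, and these counts were not set against other splits. The log2 fold changes of the 2 steps correlated across genes at r = -0.543 (jackknife SE 0.277 over libraries), and at -0.350 without stage 41 replicate 2. Both steps use the stage 39 libraries, and simulated stages without any effect gave -0.461 ± 0.0219 (SD, 20 simulations). The covariance was -0.695, against -0.672 ± 0.0516 in those simulations. Each gene was drawn independently there, so both simulated SDs leave out structure that libraries share. They may be too narrow to judge these differences. With the stage 39 libraries split so that each step had its own 3, the mean correlation over 20 splits was -0.0407, and it ranged from -0.187 to 0.253.

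**Figure D5:**
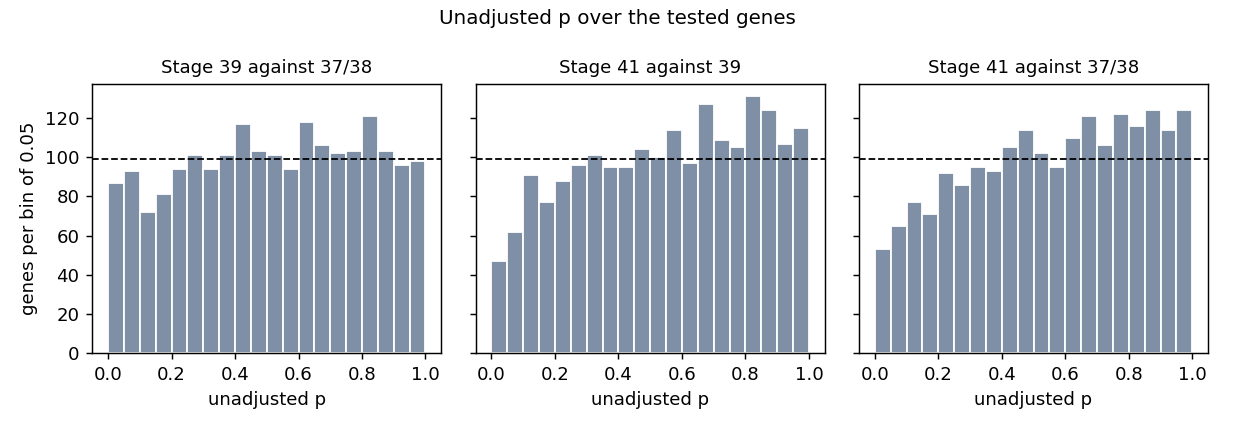
Histograms of the unadjusted p of edgeR's test over 1985 genes in the 3 stage comparisons, in bins of 0.05, with the dashed line at the 99.25 genes per bin of a flat distribution. The lowest bin holds 87, 47 and 53 genes, under the line in each comparison. Other groupings of the same libraries gave medians of 74, 51 and 49 genes at an unadjusted p under 0.05.

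The size of change that these libraries could show was limited by their spread, with a biological coefficient of variation of 1.17 as edgeR estimated it. Their counts limited it too, and the part of each was not separated. In simulated counts with the same 1985 genes, edgeR called 12.8% of 4-fold and 77.6% of 32-fold rises for stage 39 against 37/38, and 4.80% and 55.2% of falls of those sizes. For stage 41 against 39 it called 14.4% and 90.4% of such rises and 7.20% and 49.6% of such falls. For stage 41 against 37/38 it called 8% and 81.6% of rises and 4.80% and 40.8% of falls. A change of 4-fold was thus mostly not detected in these simulations. They changed 200 of the 1985 genes together, and the adjusted threshold is stricter when fewer genes change. They also drew each gene independently. The shares called, those of 32-fold changes included, may therefore be too high for a single changed gene in the real libraries.

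Genes with counts in every library were measured more closely. This set was chosen after seeing the data. A gene without counts in any 1 library cannot be in it, so it leaves out genes absent from a stage. Of the 458, 456 passed the filter, and the unadjusted 95% interval of the limma-voom fold change lay wholly within 4-fold in either direction for 336 of them between stages 39 and 37/38, 328 between 41 and 39 and 325 between 41 and 37/38. The median half-width of these intervals was 1.22, 1.31 and 1.25 on the log2 scale. Among the other 1529 tested genes the interval lay within 4-fold for 85, 56 and 82. Of the 456 genes, 18, 9 and 16 had an unadjusted p under 0.05 in edgeR in the 3 comparisons, where a flat distribution of p would give 22.8. When p was adjusted over these genes only, 0 passed the threshold.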

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

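The tests in this part that were chosen only after the result was seen are those of stage as the whole cause of the shared gene set, of the relations of genes detected at equal depth to total counts, to the share of genes seen once and to the share of the 10 most abundant genes, with the fits that leave out pairs of stage 39 libraries. A search by Dixon's gap for single libraries far from the rest of their stage covered 30 groups of values and found 3. Its cutoffs give about 1 in 20 by chance for normally distributed values, which CPM with many zeros are not. Stage 41 replicate 2 had 748720 counts, against 67834 to 204903 in the other 4 libraries of its stage. TRINITY_DN27721_c0_g1 had 55.0 CPM in stage 37/38 replicate 4, against 0 to 16.9 in the other 5, a value of 4 counts. TRINITY_DN31429_c0_g2 had 1090 CPM in stage 41 replicate 3, against 0 to 268 in the other 4. Both genes were picked from these data for their small p.

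Stage 39 replicates 2 and 4 shared a profile: their log2(CPM + 1) values correlated at r = 0.621, where the highest correlation of either with any other library was 0.532. The values argue against a few very abundant genes and against unequal depth, since without the 50 most abundant genes the pair's r was 0.524 against at most 0.416, and at 60000 counts per library 0.543 against at most 0.433. Replicates 2 and 4 were chosen as a pair from these same data. Values that set them against the other stage 39 libraries are thus no independent test of stage as the whole cause. Genes were picked from only 1 library of the pair, at least 8-fold above the median of the 15 libraries outside it. That median includes the other 4 stage 39 libraries. The 116 genes picked from replicate 2 stood at 4.20 (median log2 above that level) in replicate 4. In the other 4 stage 39 libraries they stood at 0.28 ± 0.59 (SD of library medians). The 147 picked from replicate 4 stood at 3.26 in replicate 2 and at 0.10 ± 0.50 in those 4. These values show that libraries of stage 39 differed from each other in these genes. What stays open is a difference in what the explants held, such as other tissue carried along when they were cut, or a difference between cultures or embryos, which could place the same genes in stage 41 replicates 1 and 3 as well. Without gene names no marker of a cell type could be examined, so this remains an untested hypothesis.

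At 60000 counts, stage 39 replicate 5 showed 5848 genes and stage 41 replicate 5 showed 2696, a ratio of 2.17 with depth made equal by thinning. A cause other than depth that goes with the total count stays open, since over the 17 libraries this number rose with the total before thinning (r = 0.719, permutation p = 0.001, adjusted 0.002, and rho = 0.750, permutation p = 8e-04, adjusted 0.0032), with r = 0.774 (permutation p = 5e-04) and rho = 0.693 (permutation p = 0.0051) without the 2 libraries farthest from the median and rho of 0.650 and 0.667 within the letter runs. Few distinct molecules at the start of some libraries may give such a pattern, and the share of genes seen once rose with the number of genes (r = 0.608, permutation p = 0.0093, adjusted 0.0124, and rho = 0.517, permutation p = 0.0341, adjusted 0.0455). Without the 2 farthest libraries those values were r = 0.522 (permutation p = 0.0442) and rho = 0.375 (permutation p = 0.1692), with rho of 0.700 and 0.405 within the runs, so the rank relation rests partly on those libraries, and these values cannot tell few molecules apart from explants that express fewer genes. Both measures come from the same 60000 counts, where more genes leave fewer counts for each, so part of this relation may be arithmetic. A larger share of the 10 most abundant genes stays open too (r = -0.244, permutation p = 0.3441, adjusted 0.3441, and rho = -0.218, permutation p = 0.4019, adjusted 0.4019, with r = -0.224 and rho = -0.164 without the 2 farthest (permutation p = 0.4235 and 0.5593) and rho of -0.583 and -0.405 within the runs), and the 4 relations were computed in 1 family.

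Under more permissive filters edgeR called 34 genes for stage 39 against 37/38 with 5 CPM in 5 libraries and 41 with none, and 8 with either filter for stage 41 against 37/38. Most of these genes had been tested under the default filter and not called: 24 of the 34, 28 of the 41 and 6 of the 8 with either filter. Chance in how libraries fall into groups is not excluded: 29 of 100 splits called as many as 34 and the highest other split called 93, and 15 of 100 splits of stages 37/38 and 41 called as many as 8 and the highest other split called 45, the real one included in each. A split with several times the real count may reflect a structure of the samples other than stage, but which libraries stood together in these splits was not examined. For stage 39 against 37/38, replicates 2 and 4 of stage 39 held over 50% of the summed CPM of 28 of the 34 and of 28 of the 41 genes, and without both libraries the calls fell to 1 and 3 and the median log2 fold change of the first calls still tested from 4.38 to 0.74 (30 of the 34) and from 4.47 to 0.53 (41 of the 41), where leaving out any of the 6 pairs of other stage 39 libraries gave 4.77 to 4.94 and 4.75 to 5.05. A stage effect present in part of the explants is not excluded by these values.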

How the results depend on the processing

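The 5 tests kept their count of 0 called genes in edgeR with DESeq2 size factors, the letter run as a term and each of the 17 libraries left out, and in limma-voom; the 3 stage contrasts kept it also with library size only, the 2 stages alone, the first letter run and the test against a fold of 1.5. Leaving out 1 library gave 0 to 0 calls, with 50 to 132, 29 to 112 and 40 to 140 genes at an unadjusted p under 0.05 in the contrasts. DESeq2 called 17 genes for stage 39 against 37/38, with an adjusted p of NA for 1310 of 1985, and 1 for the later minus the earlier step. Adjusted over all tested genes, a setting added after seeing the data, it called 5 for 39 against 37/38, and 2 without stage 39 replicates 2 and 4. Without any filter the calls were 41 for 39 against 37/38, 10 for 41 against 39, 8 for 41 against 37/38, 68 for any difference and 81 for the step difference. There 3272, 2806, 2348, 3627 and 3399 of 16101 genes had an unadjusted p under 0.05 in the same order. This is far more than a flat distribution gives, so p-values without a filter may be too small. The filter of 5 CPM in 5 libraries, planned as a stricter one, kept 7649 genes, since 5 CPM is few counts at these totals, and gave 34, 4 and 8 in the contrasts. With it 582, 425 and 463 genes had an unadjusted p under 0.05 in edgeR. These counts are also above a flat distribution, so p-values with this filter may be too small as well. The second letter run alone gave 4 for 41 against 37/38; the cause was not tested. Settings chosen after seeing the data left out stage 39 replicates 2 and 4: 0 calls in all 5 tests with the default filter, 1, 2 and 5 in the contrasts with 5 CPM, 3, 5, 9, 13 and 2 in the 5 tests without a filter, and with DESeq2 2 for 39 against 37/38, 1 for 41 against 37/38 and 1 for the step difference. Counts summed per assembly component, and libraries of at least 100000 counts, gave 0 in all 5. With the replicate block, edgeR called 0 in all 5 tests, with 51, 30, 35, 33 and 59 genes at an unadjusted p under 0.05; same-numbered libraries deviated from their stage means with correlations of -0.151 to 0.0841, and 0 libraries correlated best with their own number, so the numbers do not pair the samples. The correlation of the steps was -0.0407 with split stage 39 libraries, which removes the shared ones, and -0.632 to -0.350 with 1 library left out, and the first component held 23.9% with the 500 most variable genes. The 4 genes named for stage 41 against 37/38 kept their sign in all 33, 29, 34 and 32 settings in which each was tested, some of these added after seeing the data, and passed the threshold in 4, 4, 5 and 0, with lowest adjusted p of 0.00897, 3.36e-08, 2.84e-06 and 0.313. They were picked as extremes of this contrast, and most settings use nearly the same libraries, so a kept sign is no independent support. The first 3 passed in edgeR without a filter (0.0402, 0.000577 and 0.000218) and with 5 CPM, TRINITY_DN85_c0_g1 also in the second letter run (0.00236), and the remaining passes came with stage 39 replicates 2 and 4 left out. Among these, the 3.36e-08 of TRINITY_DN31429_c0_g2 came from DESeq2 with a log2 fold change of 23.5. This gene had no count at stage 37/38, and DESeq2 with all libraries gave 7.95 (adjusted p = 0.75). Its fold and p are thus unstable, and it is the 1 gene that DESeq2 called for 41 against 37/38 without those libraries. With library size only, the median log2 fold change of 39 against 37/38 was -0.12 in place of 0.12. The gene list tests and their alternatives were not run for lack of gene names. Low totals limit the tests to genes of high counts, 1985 of 19649; whether the table holds all reads is not given in the sources used here.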

Other observations

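The tests of other splits for the 5 counts of called genes, and the relation of genes detected to a library's mean correlation, were chosen after the values they concern had been seen. The count of 0 for stage 39 against 37/38, 41 against 39, 41 against 37/38, any difference between the stages and the later minus the earlier step was reached by 100 of 100 splits of the libraries in each case, as any split must reach a count of 0, so it says nothing about chance. As many genes at an unadjusted p under 0.05 as with the real stages were found in 45, 62, 39, 37 and 20 of 100 splits in the same order. The highest count of another split was 2, 28, 1, 39 and 62. Splits with 28, 39 and 62 calls, against 0 for the real stages, point to a structure of the samples that the stage groups do not capture. In each of these 3 splits stage 39 replicates 2 and 4 and stage 41 replicates 1 and 3, 4 libraries, stood in 1 group. None of the 4 is of stage 37/38, so a stage effect in part of the explants is not excluded.

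Presence and absence of transcripts was tested as a coarser sign of stage, with the prediction written before the result was seen. A gene was counted when it had a count in all or all but 1 library of a stage and in at most 1 library of the other stage. There were 100 such genes between stages 37/38 and 39, 201 between 39 and 41 and 160 between 37/38 and 41, of which 76 were mostly in stage 37/38 and 84 mostly in stage 41. As many or more were found in a share of 0.747, 0.610 and 0.766 of all 462 splits of the libraries, so these counts are not beyond what arbitrary groupings of the same libraries give. The libraries were not thinned to equal depth for this test. Splits of deep against shallow libraries may therefore hold more such genes, and an effect of stage is not excluded. The highest split of stages 37/38 and 41 gave 758 such genes.

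The number of genes detected at 60000 counts also rose with a library's mean correlation to the other 16 libraries at that depth (r = 0.755, permutation p = 4e-04, adjusted 0.0016, and rho = 0.672, permutation p = 0.0044, adjusted 0.0088, n = 17). Without the 2 libraries farthest from the median r was 0.672 (permutation p = 0.0068) and rho 0.536 (permutation p = 0.043). Within the letter runs rho was 0.583 and 0.810. Both measures come from the same thinned counts, so they are not independent of each other.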
